A study of Mus musculus with 6 samples.

How the data were processed

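RNA sequencing was done on 6 libraries of 100 sorted cells each from C57BL/6 mouse embryos that carried a tdTomato reporter knocked into the Hlf locus. Tissues were digested with 0.125% collagenase for 1 h at 37 °C, cells were sorted, and the lysate went straight into cDNA synthesis. The 3 Hlf-negative libraries came from yolk sac at embryonic day 9.5, and the 3 Hlf-positive libraries came from caudal-half tissue at embryonic day 10.5. Cells of both groups were sorted as c-Kit positive and CD45 negative.

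Each deposited file lists RefSeq transcripts with total transcript reads, which are whole-number counts that the authors did not normalize. The same files hold deposited RPKM values, which the authors normalized for transcript length and the number of reads. Per the file headers, reads were trimmed before counting, and the genome build was mm10. The aligner, the counting program and their settings are not given in the sources used here. The tables held 29595 transcripts of 21966 gene symbols. The RPKM values were checked on 11448 transcripts with more than 50 reads in every library and were proportional to reads over a fixed length, with 1 denominator per library. No pair of libraries was identical. Gene coordinates came from the RefSeq annotation of GRCm38, the assembly behind mm10: 20319 symbols were matched by transcript, 737 by symbol, and 910 had no match. Of the symbols, 4514 had several transcripts and 898 had transcripts at more than 1 locus.

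Total transcript reads per library ranged from 18166318 to 20972670, so that a floor of 3 reads equalled 0.143 to 0.165 CPM. Reads without molecular identifiers are not independent molecules, and all intervals (95%) and floors given here cover counting error only. Where a group had 0 reads of a gene, the fold was computed against 3 reads over the group and is a lower bound. Where it had 1 to 3 reads, the ratio is given with its exact counting interval.

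The comparison, the filters, the 40 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The plan named limma-trend on log2(RPKM + 1) for files of RPKM, and edgeR quasi-likelihood for files of counts. Since the files held counts, edgeR was the main test and limma-trend became an alternative. For each symbol the transcript with the highest mean RPKM was used, and symbols with RPKM of at least 1 in at least 3 of the 6 libraries were tested. In any list, a gene below that level in all libraries of 1 group could pass only by reaching it in every library of the other. For such genes the filter fixed the direction. Counts were scaled by TMM with library totals over all transcripts, and quasi-likelihood F tests (two-sided) compared Hlf-positive with Hlf-negative libraries. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p below 0.05 were called. Levels are TMM-scaled CPM (counts scaled to library size) with the SD over 3 libraries, and log2 fold changes are Hlf-positive minus Hlf-negative with the SE of the fit.

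Gene lists with at least 3 tested members (37 of 40) were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01, and their p-values were adjusted over the lists. Members called were also counted after adjustment over the list alone. Named genes were Hlf, Kit and Ptprc, the 10 called genes with the largest increase and the 10 with the largest decrease, and up to 4 called members of each list with the largest change. The genes of largest change had to be separated between the groups, with a mean RPKM of at least 5 in the higher group, and predicted, microRNA, snoRNA, ribosomal RNA and pseudogene symbols were left out. A list with no called member was represented by the member with the smallest p. This rule gave 124 genes. Exact two-sided permutation tests over the 20 relabellings of the libraries were run for Hlf, Kit and Ptprc.

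The alternatives were pseudocounts of 0.1 and 5 in limma, no filter, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without a trend, array weights, a replicate block (edgeR), summed transcripts per symbol and each library left out. Quantile normalization and array weights, like the pseudocounts, were run in limma on log2 RPKM and so changed the test as well, and limma-trend is their like-for-like value. For lists, camera with an estimated correlation was also run, and fry, which tests a list against no change and not against other genes. Ranges over the alternatives of a list include both. Alternatives chosen after seeing the data were limma-trend, DESeq2, library totals without TMM, a term for libraries with a high or low share of reads on transcripts, each of those sets alone, and removal of a smooth trend on transcript length (lowess span 0.3) from each library. The test was also run on simulated data of 3 against 3 libraries with 9697 genes. It called 12%, 80%, 96% and 100% of genes changed by 1, 2, 3 and 4 on the log2 scale (50 genes each), with 9 false calls among 153.

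Mitochondrially encoded genes had 0 entries in the tables, so that list was not analysed here. The computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.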

Results

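Gene expression was measured in 6 RNA sequencing libraries of 100 sorted mouse cells each, with 3 libraries of Hlf-negative cells from the yolk sac at embryonic day 9.5 and 3 of Hlf-positive cells from caudal-half tissue of the embryo at embryonic day 10.5. Hlf encodes a PAR bZIP transcription factor of hematopoietic stem cells, and the sort read its expression from a tdTomato reporter. All cells carried c-Kit and lacked CD45, and the labels call both groups nascent hematopoietic cells. The Hlf-negative libraries held 20262402, 19274301 and 20972670 transcript reads, and the Hlf-positive libraries held 20328827, 18166318 and 20061819. In the same order, 9150, 9126, 8437, 9867, 9546 and 9696 gene symbols reached an RPKM of 1.

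The first principal component held 72.4% of the variance and separated the groups. The second held 17.5% and set Hlf-negative replicate 3 (46.64) apart from Hlf-negative replicates 1 (−32.26) and 2 (−33.48). Across genes, which are not independent replicates, Hlf-negative replicates 1 and 2 had a correlation of 0.983, and each had 0.909 with replicate 3. Pairs of Hlf-positive libraries lay between 0.954 and 0.977, and pairs across groups between 0.70 and 0.867. Some endoderm transcripts were high in Hlf-negative replicate 3 alone, such as Ttr, with an RPKM of 34.3 against at most 0.436 in every other library, while others were not, such as Trf (2.39 there and 6.72 to 16.2 in Hlf-positive libraries).

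**Figure D1:**
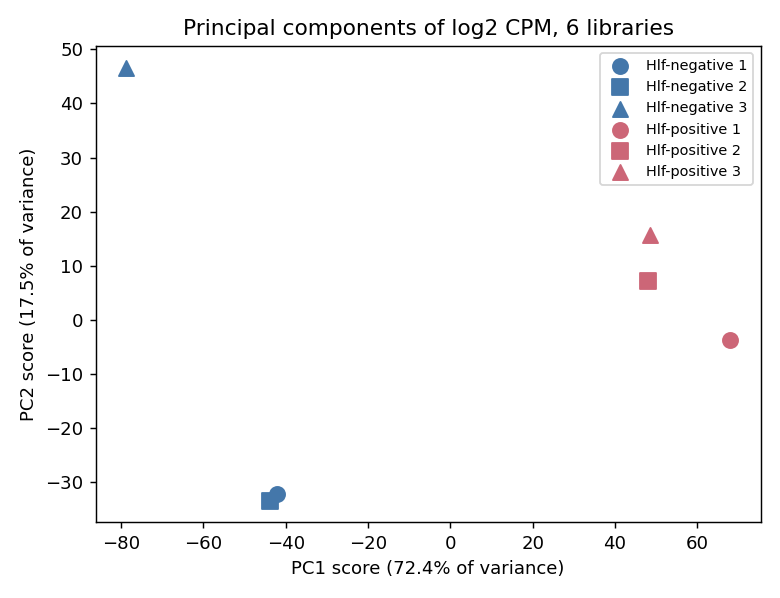
Principal components of the 6 libraries, with the first (72.4% of variance) on the x axis and the second (17.5%) on the y axis, and 1 point per library. The 3 Hlf-positive libraries lie at positive values of the first component and the 3 Hlf-negative libraries at negative values, with Hlf-negative replicate 3 apart on the second.

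The comparison asked how the transcriptome of Hlf-positive cells of caudal-half tissue differed from that of Hlf-negative cells of the yolk sac. The stem cell regulator Mecom averaged 7.94 ± 2.52 TMM-scaled CPM in Hlf-negative and 335 ± 76.1 in Hlf-positive libraries (SD, n = 3 per group), and the netrin receptor family member Neo1 went from 3.72 ± 0.855 to 105 ± 15.7. The imprinted transcription factor Plagl1 rose from 50.1 ± 22.6 to 1688 ± 553 and the imprinted growth factor Igf2 from 28.3 ± 8.68 to 998 ± 334. In the other direction, the laminin chain Lama1 fell from 272 ± 53.8 to 21.2 ± 6.00, the hyaluronan receptor Lyve1 from 87.9 ± 28.4 to 7.21 ± 0.633, and carbonic anhydrase Car2 from 327 ± 92.5 to 47.4 ± 11.97. Each of these genes was separated between all 3 Hlf-positive and all 3 Hlf-negative libraries, which the naming rule required of Lama1 and Lyve1. Chance separates 10% of genes, but these genes were picked for large changes, so separation lends no further support. Their log2 fold changes with SE were 5.40 ± 0.320 for Mecom (adjusted p = 0.000832), 4.82 ± 0.256 for Neo1 (0.000832), 5.07 ± 0.441 for Plagl1 (0.00157), 5.14 ± 0.361 for Igf2 (0.001), −3.68 ± 0.285 for Lama1 (0.00136), −3.61 ± 0.303 for Lyve1 (0.00146) and −2.78 ± 0.290 for Car2 (0.00248). On GRCm38, Mecom spans 29951296 to 30509759 of chromosome 3, Neo1 58874679 to 59036614 of chromosome 9, Plagl1 13090832 to 13131694 of chromosome 10, Lama1 67697127 to 67822645 of chromosome 17, Lyve1 110850607 to 110862953 of chromosome 7 and Car2 14886269 to 14900770 of chromosome 3.

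Of 9697 genes tested, 1132 were higher and 439 lower in Hlf-positive cells, so that 72.1% of the called genes were higher. That share depended on the processing: limma-trend on log2 RPKM gave 840 higher and 391 lower (68.2% higher). Within limma, quantile normalization gave 929 higher and 694 lower (57.2% higher) and array weights 1583 higher and 3120 lower (33.7% higher). None of the main calls (0) was called in the other direction under any alternative run. Without 1 library, the numbers of higher genes among all called were 742 of 945 (without Hlf-negative replicate 1), 703 of 882 (Hlf-negative 2), 1605 of 2723 (Hlf-negative 3), 679 of 842 (Hlf-positive 1), 706 of 829 (Hlf-positive 2) and 723 of 869 (Hlf-positive 3), against 1132 of 1571 with all libraries. The share of reads on transcripts was an estimate, since total reads were inferred from the RPKM values and reference transcript lengths. Libraries also split by that share, across the groups: 46.378% and 46.669% in Hlf-negative replicates 1 and 2 and 46.358% in Hlf-positive replicate 1, against 39.209%, 39.542% and 40.722% in the others. Within the first set 1963 genes were higher and 1564 lower, and within the second 2515 and 2557, with the lone library of a group assumed to vary like the others. With the set as a term, 1890 were higher and 1598 lower. Reporter status, tissue and stage changed together and could not be told apart. The labels do not say whether libraries came from separate embryos or litters, so the p-values measure the spread between these samples.

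**Figure D2:**
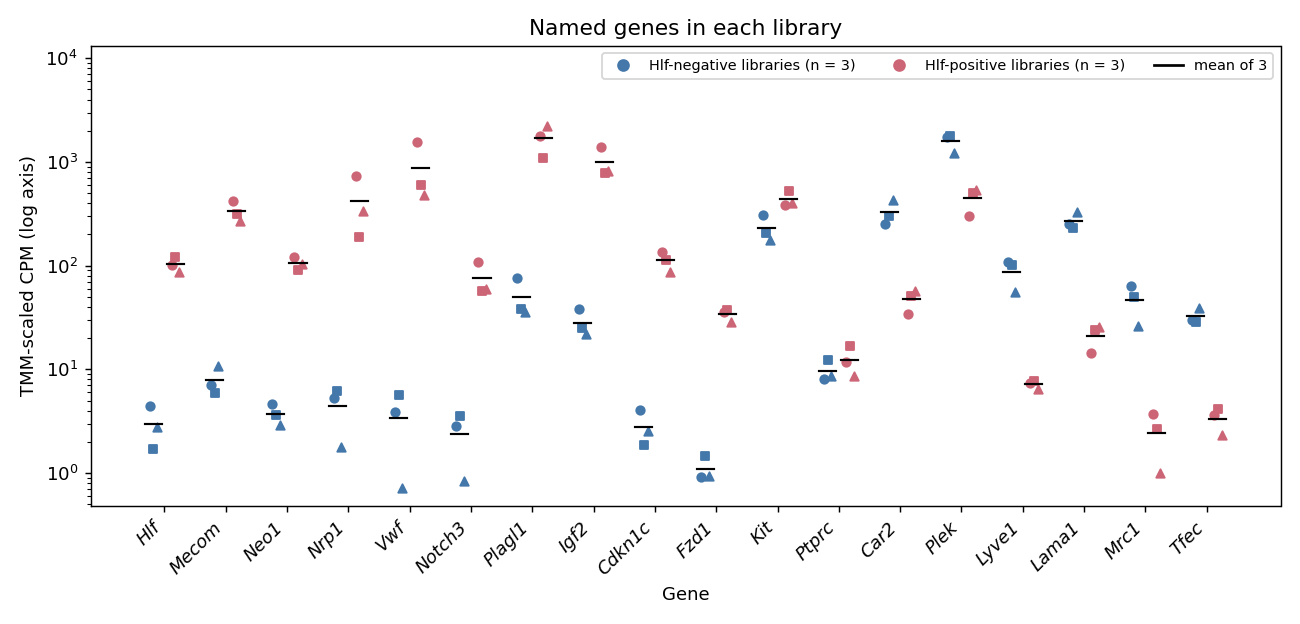
Expression of 18 named genes in TMM-scaled CPM on a log axis, with 1 point per library and a black bar at the mean of 3 libraries per group. Mecom rises from a mean of 7.94 to 335 and Vwf from 3.43 to 876, while Lama1 falls from 272 to 21.2, and Ptprc overlaps between the groups.

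The sort genes gave different results. Hlf averaged 2.98 ± 1.38 CPM in Hlf-negative and 103 ± 17.1 in Hlf-positive libraries, a log2 fold change of 5.11 ± 0.394 (SE, adjusted p = 0.00136). It lies on chromosome 11 from 90336535 to 90390917. Kit, the receptor that both gates required, averaged 230 ± 68.4 and 439 ± 79.5, a log2 fold change of 0.93 ± 0.248 (adjusted p = 0.0484). The Kit call was lost without Hlf-negative replicate 2 (adjusted p = 0.122), Hlf-positive replicate 1 (0.1), Hlf-positive replicate 2 (0.159) and Hlf-positive replicate 3 (0.111). Ptprc, which encodes CD45, averaged 9.63 ± 2.32 and 12.4 ± 4.07 and was not called (log2 fold change 0.37 ± 0.320, adjusted p = 0.45), and quantile normalization turned its sign (−0.24). Exact two-sided permutation tests gave p = 0.1 for Hlf and Kit, the smallest value that 3 against 3 allows, and p = 0.5 for Ptprc.

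Among 27 tested hematopoietic stem cell transcription factors, 11 were higher, 1 was lower and 15 were not called (12 higher and 1 lower adjusted over the list alone). Hlf, on whose reporter the groups were sorted, is 1 of the higher genes, and the list was not tested without it. The list was higher against other genes (median log2 fold change 0.48, adjusted p = 0.00303), with adjusted p = 0.169 with an estimated correlation, and it was called in 24 of its 25 alternatives. Mecom is also in the arterial endothelial list, and endothelial and mesenchymal markers were higher in the same libraries. Besides Hlf and Mecom, the repressor Gfi1 rose from 0.761 ± 0.780 to 56.7 ± 9.63 CPM (log2 fold change 6.20 ± 0.680, and 7.49 without Hlf-negative replicate 2) and Tcf15 from 0.149 to 3.11 (4.30 ± 0.565). The lower gene was Gfi1b, an erythroid and megakaryocytic relative of Gfi1 (−2.37 ± 0.460, adjusted p = 0.017, and −1.71 with summed transcripts), whose adjusted p was 0.051 without Hlf-negative replicate 1, 0.0506 without Hlf-negative replicate 2, 0.0568 without Hlf-positive replicate 1 and 0.0634 without Hlf-positive replicate 2. Runx1 and Gata2, required for the emergence of blood stem cells and named here after their values were seen, had log2 fold changes of −0.37 ± 0.143 (adjusted p = 0.129) and 0.13 ± 0.141 (0.56).

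Of 28 stem cell surface and signalling genes, 20 were higher, 2 lower and 6 not called (23 higher and 2 lower adjusted over the list alone). Their median log2 fold change was 1.55 (adjusted p = 2.58e-08), with adjusted p = 0.169 with an estimated correlation. Neo1 was among them, and the chemokine receptor Cxcr4 rose from 0.431 ± 0.462 to 35.6 ± 14.7 CPM (6.39 ± 0.809, adjusted p = 0.0043, and 7.64 without Hlf-negative replicate 3). Prom1 had 2 reads over the Hlf-negative and 616 over the Hlf-positive libraries, a ratio of 299.8 (95% counting interval 82.6 to 2481), and both Hlf-negative reads came from replicate 1, without which its fitted log2 fold change went from 7.99 to 10.65, against a group at 0 and so no bound. With summed transcripts it was 6.66. The interferon-induced membrane proteins Ifitm1 (4.42 ± 0.691) and Ifitm3 (3.48 ± 0.482) also rose (5.69 and 4.19 without Hlf-negative replicate 3, and Ifitm1 3.78 with summed transcripts). Endothelial markers, several of them in this list, were higher in the same libraries, and mesenchymal markers moved the same way. Col3a1 had an RPKM of 0.831, 0 and 0.0168 in Hlf-negative and 15.0, 13.8 and 53.4 in Hlf-positive libraries. Its log2 fold change was 6.72 (adjusted p = 0.0388), 11.32 without Hlf-negative replicate 1 and 5.77 without Hlf-positive replicate 3, and its call was lost without Hlf-negative replicate 2 (adjusted p = 0.0603) or Hlf-positive replicates 1 (0.0884), 2 (0.0882) or 3 (0.107).

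All tested Hox genes were higher: 3 of 3 in the Hoxa cluster, 1 of 1 in Hoxb and 3 of 3 in Hoxc and Hoxd, with the same counts adjusted over the list alone. The lists hold 11, 10 and 18 genes, of which 0 reached an RPKM of 1 in any Hlf-negative library. A Hox gene could thus pass the filter only by reaching it in every Hlf-positive library. The filter therefore fixed the direction of these counts and of the list tests below. Summed over all listed genes, RPKM was at most 0.1065, 1.36 and 0.133 in Hlf-negative libraries. In Hlf-positive libraries it was at least 7.15, 4.34 and 9.635. Hox genes mark position along the body axis. Hoxa10 had 0 reads over the Hlf-negative and 391 over the Hlf-positive libraries, at least 127-fold higher. Hoxb9 (0 against 720 reads) was at least 234-fold higher and Hoxd10 (0 against 478) at least 155-fold. Hoxa9 had 1 against 667 reads, a ratio of 649 (95% counting interval 116 to 25680). The fitted medians were 8.88 for Hoxa (8.45 with genes of 0 reads at their bound, adjusted p = 9.08e-05) and 7.98 for Hoxc and Hoxd (7.28, adjusted p = 0.000456), each with adjusted p = 0.169 with an estimated correlation. The Hoxb list was too small for a list test in the main setting, and camera called it in the 1 alternative that could test it (adjusted p = 0.000214). The tissues differed along with Hlf, and mesenchymal markers such as Col3a1 (an RPKM of at least 13.8 in each Hlf-positive library and at most 0.831 in each Hlf-negative library, with the calls as given above) were higher in the same libraries.

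Arterial and hemogenic endothelial genes were the list with the smallest p by camera with the preset correlation, but not by fry or with an estimated correlation. Of their 22 tested members, 20 were higher, 0 lower and 2 not called (21 higher adjusted over the list alone), with a median log2 fold change of 3.90 (adjusted p = 4.63e-13, and adjusted p = 0.211 with an estimated correlation). Listed genes at an RPKM of 1 numbered 7, 7 and 6 of 30 in Hlf-negative libraries and 27, 23 and 22 in Hlf-positive libraries. Members below it in every Hlf-negative library, such as Gja5, Bmx and Nrp1, passed the filter only by reaching it in every Hlf-positive library. For those members the filter fixed the direction. The list was called in 24 of its 25 alternatives, also without the filter. The semaphorin and VEGF co-receptor Nrp1 rose from 4.41 ± 2.33 to 417 ± 279 CPM (6.55 ± 0.740, adjusted p = 0.00301, and 5.88 without Hlf-positive replicate 1). Bmx rose by 8.62 ± 0.919 on the log2 scale (7.83 without Hlf-positive replicate 1 and 10.09 without Hlf-negative replicate 1). Gja5, an arterial gap junction gene, had 1 against 14709 reads, a ratio of 14320 (95% counting interval 2569 to 565500), or 2187 (392 to 86450) without Hlf-positive replicate 1. Its RPKM was 97.0 in Hlf-positive replicate 1 against at most 5.06 elsewhere. Of 29 pan-endothelial genes, 17 were higher, 1 lower (Lyve1) and 11 not called (23 higher and 1 lower adjusted over the list alone). Their median was 2.10 (adjusted p = 3.36e-07, and adjusted p = 0.361 with an estimated correlation). Emcn rose by 5.90 ± 1.02 (4.48 without Hlf-positive replicate 1) and Mmrn2 by 4.32 ± 0.703 (3.28 without it). Of 21 Notch pathway genes, 9 were higher, 0 lower and 12 not called (10 higher adjusted over the list alone), with a median of 0.57 (adjusted p = 9.08e-05, and adjusted p = 0.361 with an estimated correlation). Notch3 rose from 2.41 ± 1.42 to 75.4 ± 29.4 CPM (4.96 ± 0.583), and the Notch targets Hey1 (4.44 ± 0.712) and Hey2 (4.46 ± 0.783) rose as well (3.35 and 3.32 without Hlf-positive replicate 1). Hey1 and Hey2, like Notch1, Notch4, Dll4, Jag1, Jag2 and Heyl, are in both the Notch and the arterial list, so these lists are not separate results. Arterial transcripts summed to an RPKM of 673.2 in Hlf-positive replicate 1, 177.7 and 171.2 in the other Hlf-positive libraries, and 17.6 to 24.8 in the Hlf-negative libraries.

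**Figure D3:**
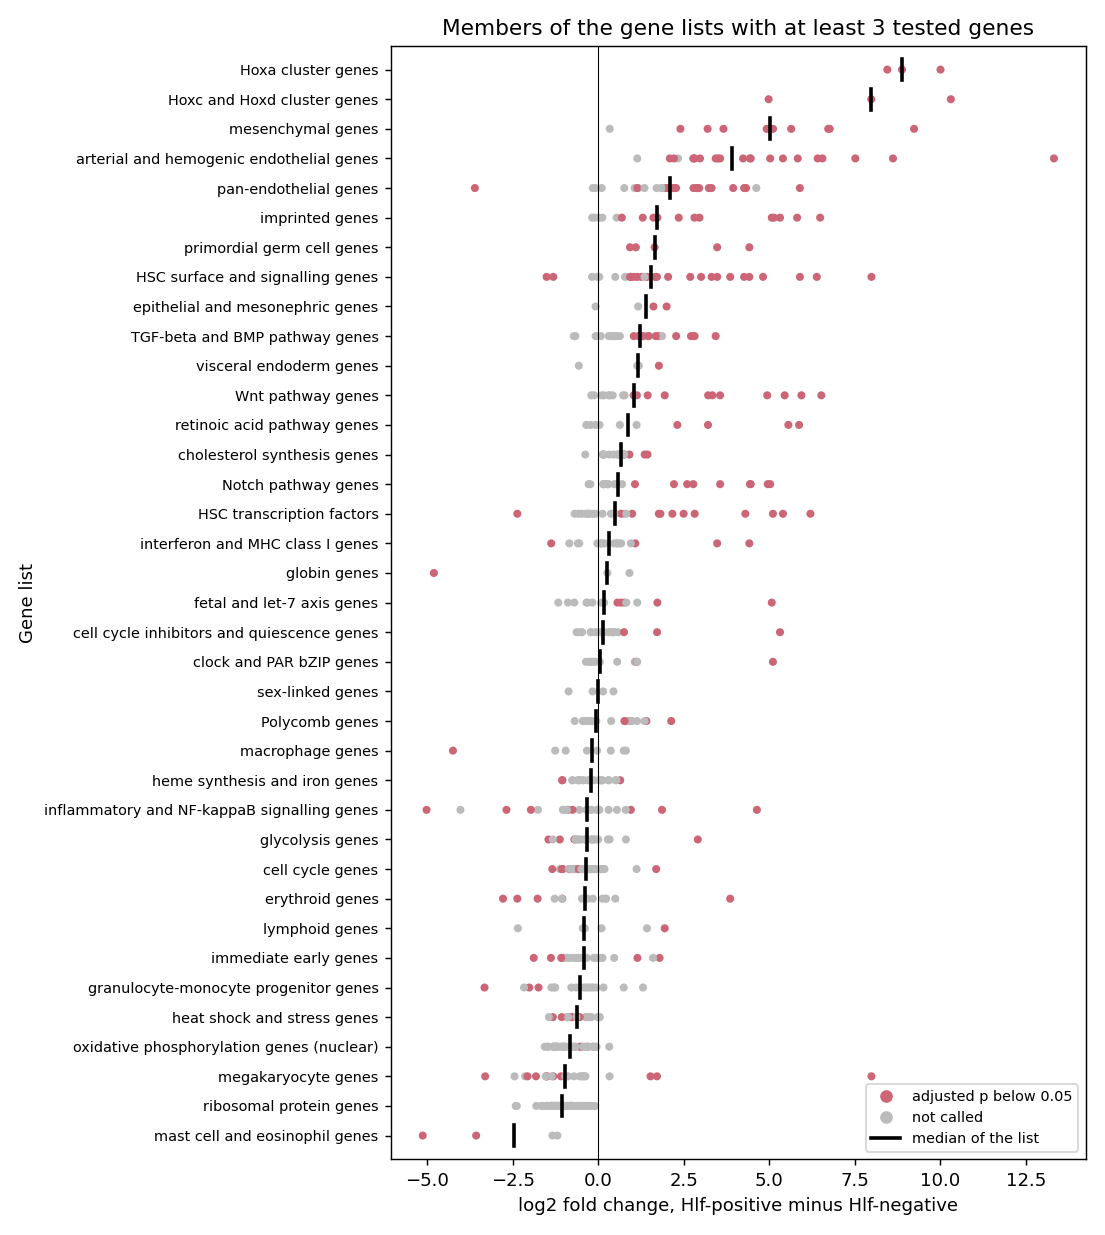
Log2 fold changes (Hlf-positive minus Hlf-negative) of the tested members of each gene list, with red points for adjusted p below 0.05, grey points for genes not called and a black bar at the list's median. Arterial genes have a median of 3.90, megakaryocyte genes −0.96 and ribosomal protein genes −1.07, and fitted values of genes with 0 reads in a group are not bounds.

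Of 21 Wnt pathway genes, 11 were higher, 0 lower and 10 not called (13 higher adjusted over the list alone), with a median of 1.04 (adjusted p = 4.75e-07, and adjusted p = 0.169 with an estimated correlation). The receptors Fzd1 (1.10 ± 0.308 to 34.1 ± 4.65 CPM, 4.94 ± 0.292) and Fzd2 (6.52 ± 0.450) and the ligand Wnt2 (5.45, adjusted p = 0.00324, and 4.74 without Hlf-positive replicate 3) rose. Of 28 TGF-beta and BMP pathway genes, 13 were higher, 0 lower and 15 not called (14 higher adjusted over the list alone), with a median of 1.23 (adjusted p = 1.2e-06, and adjusted p = 0.169 with an estimated correlation). Smad6 and Smad7, which inhibit this pathway, rose by 2.82 and 2.79 on the log2 scale, and the ligand Bmp4 by 3.43 (2.64 without Hlf-positive replicate 3). Smad6 and Bmp4 are also in the arterial list. Of 10 retinoic acid pathway genes, 4 were higher, 0 lower and 6 not called (5 higher and 1 lower adjusted over the list alone), with a median of 0.88 (adjusted p = 0.0315, and adjusted p = 0.211 with an estimated correlation). Aldh1a2, which makes retinoic acid, rose by 5.87 (7.24 without Hlf-negative replicate 1), and Cyp26b1, which degrades it, by 5.56. The retinoic acid call was lost with a mean RPKM of at least 5 (adjusted p = 0.122), with the read-share set as a term (0.0701), within the set of higher share (0.0906) and with the length trend removed (0.0535), over a range of 9.39e-05 to 0.211 in its 25 alternatives. In the same libraries 10 of 11 mesenchymal genes were higher, 1 was not called and 0 were lower, the same counts as adjusted over the list alone. Of all 26 listed genes, 2, 3 and 2 reached an RPKM of 1 in Hlf-negative and 13, 13 and 18 in Hlf-positive libraries. For members below it in every Hlf-negative library, such as Col1a1 and Acta2, the filter fixed the direction. The mesenchymal median was 5.02 (adjusted p = 4.75e-07, and adjusted p = 0.169 with an estimated correlation). Acta2 rose from 0.677 ± 0.373 to 74.6 ± 26.1 CPM (6.77 ± 0.490) and Col1a1 by 9.23 ± 1.56 (7.33 without Hlf-positive replicate 3, 8.64 without Hlf-negative replicate 1 and 11.69 without Hlf-negative replicate 2), and Lum reached an RPKM of 53.8 in Hlf-positive replicate 3 against at most 2.09 elsewhere.

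Imprinted genes were higher: 13 of 18 rose, 0 fell and 5 were not called (13 higher adjusted over the list alone), with a median of 1.72 (adjusted p = 4.75e-07, and adjusted p = 0.169 with an estimated correlation). With Plagl1 and Igf2, the cyclin-dependent kinase inhibitor Cdkn1c rose from 2.81 ± 1.10 to 112 ± 25.1 CPM (5.31 ± 0.367). The list of 15 fetal and let-7 axis genes had 5 higher, 0 lower and 10 not called (6 higher and 1 lower adjusted over the list alone) and was not called (median 0.17, adjusted p = 0.174). It was called with a mean RPKM of at least 5 (0.00774) and by fry (0.0362), over a range of 0.00774 to 0.562 in its 25 alternatives. The mesenchymal markers named above were higher in the same libraries, with Col1a1 at an RPKM of 3.66, 1.75 and 23.6 against at most 0.0463 in Hlf-negative libraries.

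Megakaryocyte genes were lower as a list, with 7 of 25 lower, 3 higher and 15 not called (14 lower and 3 higher adjusted over the list alone), and a median of −0.96 (adjusted p = 8.93e-05, and adjusted p = 0.32 with an estimated correlation). The platelet protein Plek fell from 1579 ± 302 to 447 ± 126 CPM (−1.82 ± 0.269), and its adjusted p was 0.0552 after quantile normalization. Slc35d3, a gene of platelet granules, fell by 2.07 on the log2 scale. The von Willebrand factor gene Vwf, which endothelial cells also express, went the other way, from 3.43 ± 2.51 to 876 ± 584 (7.99 ± 0.927, adjusted p = 0.00327, 7.29 without Hlf-positive replicate 1). The megakaryocyte call was lost within the set of lower read share (adjusted p = 0.0858), over a range of 1.41e-07 to 0.32 in its 25 alternatives.

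Of 14 erythroid genes, 4 were lower, 1 higher and 9 not called (5 lower and 1 higher adjusted over the list alone), and the list missed the threshold (median −0.40, adjusted p = 0.0577). It was called without Hlf-negative replicate 3 (adjusted p = 0.0419), Hlf-positive replicate 1 (0.0354), Hlf-positive replicate 2 (0.0491) or Hlf-positive replicate 3 (0.0399), without the filter (0.00871), in the set of higher read share (0.0164) and by fry (0.046), over a range of 0.00871 to 0.576 in its 25 alternatives. Among the called erythroid genes Car2 had the largest decrease, and genes too low to test were not ranked. Of 3 globin genes, the primitive Hbb-bh1, whose transcripts map to more than 1 locus, was lower (−4.81 ± 1.04, adjusted p = 0.0246) and 2 were not called, also adjusted over the list alone. The Hbb-bh1 call was lost without Hlf-negative replicates 1 (adjusted p = 0.0521) or 2 (0.0536, with a change of −3.83) and without Hlf-positive replicates 1 (0.0983), 2 (0.0912) or 3 (0.0737). The globin median (0.27) and mean (−1.21) differed in sign, and the test, which pointed lower, did not call the list (adjusted p = 0.803). Of 23 heme synthesis and iron genes, 2 were lower, 1 higher and 20 not called (2 lower and 0 higher adjusted over the list alone), with a median of −0.22 (adjusted p = 0.174, called by fry alone at 0.046, over a range of 0.046 to 0.576).

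Of 4 mast cell and eosinophil genes, 2 were lower and 2 not called (4 lower adjusted over the list alone), with a median of −2.45 (adjusted p = 0.00357, and adjusted p = 0.211 with an estimated correlation). The interleukin-33 receptor Il1rl1 fell from 107 ± 3.22 to 3.02 ± 3.66 CPM (−5.13 ± 0.957), with −6.81 without Hlf-positive replicate 3 and adjusted p = 0.0691 without Hlf-positive replicate 1. Cpa3 fell by 3.57 on the log2 scale (−2.97 without Hlf-negative replicate 3 and −4.41 without Hlf-positive replicate 3), with adjusted p = 0.0589 without Hlf-positive replicate 1 and 0.0759 without Hlf-positive replicate 2. Granulocyte-monocyte progenitor genes had 3 of 19 lower, 0 higher and 16 not called (6 lower and 1 higher adjusted over the list alone), with a median of −0.53 (adjusted p = 0.0118, and adjusted p = 0.361 with an estimated correlation). That call was lost without Hlf-negative replicate 3 (adjusted p = 0.0592), with a mean RPKM of at least 5 (0.162), within the set of higher read share (0.319) and with the length trend removed (0.051), over a range of 0.00107 to 0.361 in its 25 alternatives. Of 8 macrophage genes, 1 was lower and 7 were not called (2 higher and 2 lower adjusted over the list alone, median −0.18, adjusted p = 0.538), and the lower gene was the mannose receptor Mrc1 (46.6 ± 18.7 to 2.45 ± 1.36 CPM, −4.25 ± 0.565). Of 8 lymphoid genes, Tcf7 was higher (1.94 ± 0.317, adjusted p = 0.00932) and 7 were not called, with the same counts adjusted over the list alone (median −0.40, mean −0.07, adjusted p = 0.56).

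Inflammatory and NF-kappaB signalling genes had 5 of 24 lower, 3 higher and 16 not called (6 lower and 3 higher adjusted over the list alone), and the list missed the threshold (median −0.33, adjusted p = 0.0577). It was called without Hlf-negative replicate 3 (adjusted p = 0.0477) or Hlf-positive replicate 1 (0.00366) and in 5 other alternatives of its 25, over a range of 0.00366 to 0.56 in its 25 alternatives. The NF-kappaB inhibitors Tnfaip3 (−2.68 ± 0.317) and Nfkbia (−1.97 ± 0.256) and the chemokine Cxcl2 (−5.02 ± 0.859, and −4.10 without Hlf-negative replicate 3) fell, and Csf1 rose (4.64 ± 0.492, and 3.62 with summed transcripts). Interferon and MHC class I genes had 3 of 18 higher, 1 lower and 14 not called, with the same counts adjusted over the list alone (median 0.33, adjusted p = 0.174), and the list was called without Hlf-negative replicate 3 (adjusted p = 0.0209), with a mean RPKM of at least 5 (0.00385), in the set of higher read share (0.00764) and with the length trend removed (0.0344), over a range of 0.00385 to 0.966. Of 24 immediate early genes, 4 were lower, 2 higher and 18 not called (4 lower and 3 higher adjusted over the list alone), with a median of −0.41 (adjusted p = 0.0335, and adjusted p = 0.361 with an estimated correlation). Myc fell by 1.89 and Zfp36 by 1.38 on the log2 scale, and Atf3 rose by 1.79. The immediate early call was lost without Hlf-negative replicates 2 (adjusted p = 0.0529) or 3 (0.0594) and without Hlf-positive replicates 2 (0.078) or 3 (0.0517), and it was kept in 14 of its 25 alternatives, over a range of 0.00534 to 0.645.

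Cell cycle genes were lower as a list, with 7 of 48 lower, 1 higher and 40 not called (10 lower and 2 higher adjusted over the list alone), and a median of −0.35 (adjusted p = 8.93e-05, and adjusted p = 0.169 with an estimated correlation). The call was lost after quantile normalization (adjusted p = 0.132), over a range of 1.41e-07 to 0.169. Cdc6, which loads the replicative helicase, fell by 1.07 on the log2 scale (adjusted p = 0.00722). The ribonucleotide reductase gene Rrm2 fell by 1.34, with adjusted p = 0.0579 without Hlf-positive replicate 1 and 0.0561 without Hlf-positive replicate 2. Of 23 cell cycle inhibitors and quiescence genes, 3 were higher, 0 lower and 20 not called, with the same counts adjusted over the list alone (median 0.13, adjusted p = 0.184). That list was called with a mean RPKM of at least 5 (0.00327) and by fry (0.00453), over a range of 0.00327 to 0.644. They included Cdkn1c and Ndn (1.72 ± 0.242). Of 11 clock and PAR bZIP genes, 2 were higher, 0 lower and 9 not called (3 higher adjusted over the list alone, median 0.05, adjusted p = 0.21, called by fry alone at 0.000103, over a range of 0.000103 to 0.867), and Hlf was 1 of the 2. The sort on its reporter fixed the rise of Hlf, and the list was not tested without it. Of 21 Polycomb genes, 4 were higher, 0 lower and 17 not called (6 higher and 3 lower adjusted over the list alone), among them Jarid2 (1.41 ± 0.137, adjusted p = 0.00202). The Polycomb median (−0.06) and mean (0.34) differed in sign, and the test, which pointed higher, did not call the list (adjusted p = 0.56), while fry did (0.0114, over a range of 0.0114 to 0.915).

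Cholesterol synthesis genes were higher as a list, with 4 of 20 higher, 0 lower and 16 not called (11 higher adjusted over the list alone), and a median of 0.67 (adjusted p = 0.000288, and adjusted p = 0.358 with an estimated correlation). The squalene synthase gene Fdft1 rose by 1.44 (adjusted p = 0.0129). The summed RPKM of the cholesterol list was 236.4, 224.9 and 144.4 in Hlf-negative and 337.5, 246.4 and 249.8 in Hlf-positive libraries. Hlf-negative replicate 3 and Hlf-positive replicate 1 thus lay apart, and the others were close. Of 23 glycolysis genes, 3 were lower, 1 higher and 19 not called, with the same counts adjusted over the list alone, and the median was −0.33 (adjusted p = 0.0315, and adjusted p = 0.398 with an estimated correlation). The lactate transporter Slc16a1 fell by 1.12 on the log2 scale, and Ldhb rose by 2.91. The glycolysis call was lost without Hlf-negative replicates 1 (adjusted p = 0.146) or 2 (0.136) and without Hlf-positive replicate 2 (0.0677), and within the set of lower read share the list pointed higher (0.768). It was kept in 10 of its 25 alternatives, over a range of 0.000189 to 0.795. The summed RPKM of the glycolysis list was 1686 and 1754 in Hlf-negative replicates 1 and 2. In Hlf-negative replicate 3 it was 845, below the 1175, 917 and 1032 of the Hlf-positive libraries.

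Housekeeping and stress genes were lower as lists. None of the 77 ribosomal protein genes was called by edgeR, over all genes or adjusted over the list alone (0 higher, 0 lower), with 6 at an unadjusted p below 0.05, while DESeq2 called 5 lower and limma-trend 1 lower. The median of −1.07 differed from other genes (adjusted p = 1.22e-05, and adjusted p = 0.564 with an estimated correlation). The list was not called without Hlf-negative replicate 3 (adjusted p = 0.402), after quantile normalization (0.691) or with the length trend removed (0.154), over a range of 2.95e-26 to 0.691. Their summed RPKM was 59890 in Hlf-negative replicate 3, 21560 and 21530 in the other Hlf-negative libraries, and 18000, 17860 and 20770 in the Hlf-positive libraries. Rps24, the member with the smallest p, had a log2 fold change of −2.41 and was not called (adjusted p = 0.0557, and 0.0467 and 0.0482 without Hlf-negative replicates 1 or 2). Without Hlf-negative replicate 3 the change was smaller (−1.19, adjusted p = 0.004), and with summed transcripts it was −1.11 (adjusted p = 0.251). Of 44 nuclear genes of oxidative phosphorylation, 2 were lower, 0 higher and 42 not called (0 lower adjusted over the list alone), with a median of −0.83 (adjusted p = 3.53e-05, and adjusted p = 0.435 with an estimated correlation). The call was lost after quantile normalization (adjusted p = 0.0566), over a range of 1.61e-11 to 0.435, and the list's summed RPKM was 6182 in Hlf-negative replicate 3 against 2311 to 3252 elsewhere. Of 21 heat shock and stress genes, 5 were lower, 0 higher and 16 not called (8 lower adjusted over the list alone), with a median of −0.62 (adjusted p = 7.43e-05, and adjusted p = 0.211 with an estimated correlation). Asparagine synthetase Asns fell by 1.33 on the log2 scale (adjusted p = 0.00473). The heat shock call was lost after quantile normalization (adjusted p = 0.137), over a range of 2.65e-05 to 0.211.

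**Figure D4:**
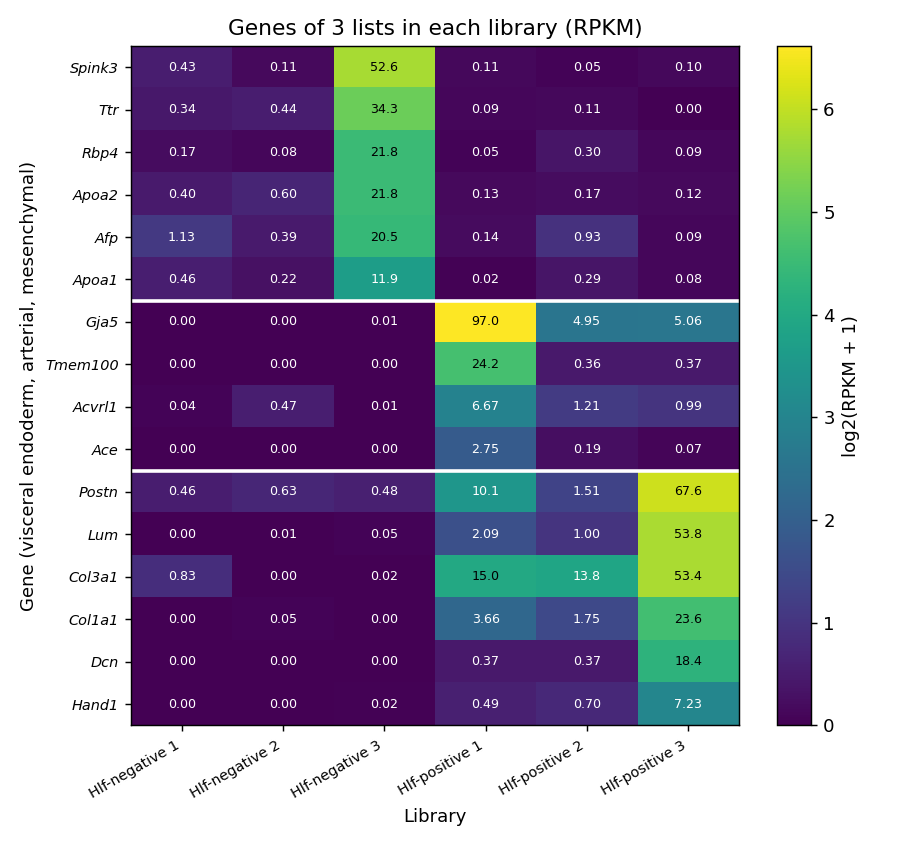
RPKM of marker genes of other cell types (rows) in the 6 libraries (columns), with colour for log2(RPKM + 1) and the RPKM printed in each cell. Ttr reaches 34.3 in Hlf-negative replicate 3, Gja5 97.0 in Hlf-positive replicate 1 and Lum 53.8 in Hlf-positive replicate 3.

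Other cell types were read from lists of their markers. Of 28 visceral endoderm genes, 4 were expressed widely enough to test, with 1 higher (the transferrin gene Trf, 1.77 ± 0.306), 0 lower and 3 not called, also adjusted over the list alone (median 1.16, adjusted p = 0.21). Per library, 5, 3 and 18 of the 28 reached an RPKM of 1 in Hlf-negative replicates 1, 2 and 3, and 3, 4 and 3 in the Hlf-positive replicates. Without the filter, the same list was lower in Hlf-positive cells (adjusted p = 0.000176), over a range of 0.000176 to 0.982. It then took in genes high in Hlf-negative replicate 3 alone, such as Spink3 (an RPKM of 52.6 against at most 0.434 elsewhere). The unfiltered test was not run without that library, so it does not show a difference between the groups. Mesenchymal genes at an RPKM of 1 numbered 2, 3 and 2 of 26 in Hlf-negative libraries and 13, 13 and 18 in Hlf-positive libraries. Of 24 primordial germ cell genes, 5 were expressed widely enough to test, and the 5 were higher, also adjusted over the list alone (median 1.65, adjusted p = 0.000382, and adjusted p = 0.169 with an estimated correlation). Per library, 4, 4 and 5 of the 24 reached an RPKM of 1 in Hlf-negative and 5, 5 and 5 in Hlf-positive libraries, and Dppa3, Pou5f1, Nanog, Tfap2c and Mael, named after their values were seen, were at most at 0.0739 in any library. The tested genes were Kit, Ifitm1, Ifitm3, Tdrd7 and Tdrkh, and Kit, Ifitm1 and Ifitm3 are also in the stem cell surface list. The Tdrkh call (1.10 ± 0.263, adjusted p = 0.0345) was lost without Hlf-negative replicates 1 (0.0984) or 2 (0.0695) and without Hlf-positive replicates 1 (0.062), 2 (0.114) or 3 (0.0748), and the Kit call as given above. Without the filter the list was not called and pointed lower (adjusted p = 0.577, the highest of a range from 7.26e-05). Of 20 epithelial and mesonephric genes, 4 were tested, of which 2 were higher, 0 lower and 2 not called, also adjusted over the list alone (median 1.39, adjusted p = 0.174), and the list was called without Hlf-positive replicate 1 (adjusted p = 0.0425), over a range of 0.0425 to 0.832. Krt18 rose by 2.00 ± 0.313. The neural list had 1 tested gene of 21, Nes, with a log2 fold change of 1.11 that was called only when adjusted over the list alone (1 higher, adjusted p over all genes = 0.0614). Of 4 sex-linked genes, 0 were called by edgeR, DESeq2 or limma-trend, and 0 had an unadjusted p below 0.05 (median −0.01, adjusted p = 0.961). In the 22 lists with 0 genes called lower by edgeR, 15 genes were lower at an unadjusted p below 0.05, and DESeq2 called 11 and limma-trend 2. In the 9 lists with 0 called higher, 4 were higher at that p, and DESeq2 called 4 and limma-trend 0.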

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

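The alternatives limma-trend, DESeq2, library totals without TMM, the read-share term, each read-share set alone and removal of the length trend were tests chosen only after the data were seen. A floor of 3 reads set a limit of 0.143 to 0.165 CPM, and at this number of libraries 12% of simulated changes of 1 on the log2 scale were called. The simulated data held fewer changed genes (153 calls against 1571 in the real data), so that share may be too low for these data. With 3 libraries per group from single tissues and stages, no alternative separates Hlf status from tissue or stage. A mean RPKM of at least 5 left too few genes for a test of 8 lists (Hoxa, Hoxc and Hoxd, globin, macrophage, mast cell, clock, epithelial and sex-linked), 3 of them called with all tested genes.

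Of 1132 genes higher and 439 lower in Hlf-positive cells, other settings gave counts that differed by over 1.5 times. A mean RPKM of at least 5 gave 338 higher and 132 lower among 5431 tested genes, and no filter gave 1910 higher among 17919. In limma on log2 RPKM, where limma-trend gave 840 higher and 391 lower, a pseudocount of 5 gave 732 higher, and lower genes numbered 694 after quantile normalization and 3120 with array weights. Lower genes numbered 1133 with DESeq2 and 689 with the length trend removed. The read-share set as a term gave 1890 higher and 1598 lower, the libraries with the higher share alone 1963 and 1564, and those with the lower share 2515 and 2557. Without 1 library the counts ranged from 679 (without Hlf-positive replicate 1) to 1605 (without Hlf-negative replicate 3) higher and from 1.2e+02 (without Hlf-positive replicate 2, where 706 of 829 called genes were higher) to 1118 (without Hlf-negative replicate 3) lower. A smaller number of libraries cannot account for the rise without Hlf-negative replicate 3. That library lay apart from Hlf-negative replicates 1 and 2 on the second principal component (46.64 against −32.26 and −33.48). Apart from this and from the numbers of genes and libraries tested, the cause was not tested. Of the 1571 calls, 1569 were kept by DESeq2, 1171 after quantile normalization and 1060 by limma-trend.

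A block for the replicate number gave 1082 higher and 380 lower, with 1289 of the 1571 calls kept and 23 lists called. Departures from the group means correlated at 0.296, −0.125 and 0.325 between libraries of the same number, so the numbers were not used as a pairing. Pairs within the set of higher read share gave 0.296 and 0.314, and pairs within the set of lower share 0.128 and 0.325. All pairs across the sets were negative (−0.362 to −0.0904). The departures thus followed the read-share set, although departures from a mean are not independent of each other. The main test had no term for that set.

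Of 37 lists, 23 were called with a preset correlation, 21 to 26 without 1 library and 24 by fry, which tests a list against no change and not against other genes. With an estimated correlation camera called 0, with 10 at an unadjusted p below 0.05. The estimates ranged from −0.29 (Hoxa genes, which also lost their call) to 0.909 (ribosomal protein genes), against the preset of 0.01. Stem cell transcription factors had an estimate of 0.0212, near the preset, and still went from adjusted p = 0.00303 to 0.169. Higher estimates alone thus do not account for the lost calls, which are no evidence of correlated genes in each list. The cause was not tested further. Camera with the preset also called 5 to 15 lists in splits that mixed the groups, where edgeR called 0 genes. Those splits still held more libraries of a group on 1 side. Part of the group difference stayed in them, so their list calls do not measure false calls. Since camera with an estimated correlation called 0 lists, a call with the preset alone is weak evidence for a list. Calls not made by fry were granulocyte-monocyte progenitor (0.0912), glycolysis (0.245), oxidative phosphorylation (0.225), ribosomal protein (0.405) and immediate early genes (0.0699), and calls gained were erythroid (0.046), heme (0.046), fetal (0.0362), clock (0.000103), cell cycle inhibitor (0.00453) and Polycomb genes (0.0114).

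Some lists changed direction, and the cause was not tested. Globin genes pointed higher with a pseudocount of 5 (adjusted p = 0.871), without a trend, with array weights or by limma-trend (0.969 each), in the libraries of higher read share (0.997) and with the length trend removed (0.557), over a range of 0.078 to 0.997. Lymphoid genes pointed higher without the filter (0.577), with summed transcripts (0.834) and by fry (0.962), over 0.316 to 0.987. Without the filter visceral endoderm genes were lower (0.000176, over 0.000176 to 0.982) and primordial germ cell genes pointed lower (0.577, over 7.26e-05 to 0.577). Polycomb genes pointed lower with a mean RPKM of at least 5 (0.593, over 0.0114 to 0.915), and glycolysis genes higher in the libraries of lower read share (0.768, over 0.000189 to 0.795). Sex-linked genes turned higher with pseudocounts of 0.1 (0.99) and 5 (0.947), without a trend, with array weights or by limma-trend (0.969 each), without TMM (0.955), in the libraries of higher share (0.73) and by fry (0.958). They ranged from 0.458 to 0.928 without 1 library, turning higher without Hlf-negative replicate 3 (0.458) or Hlf-positive replicate 1 (0.897), and from 0.315 to 0.99 over all alternatives. Ptprc had a log2 fold change of −0.24 after quantile normalization.

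For the 124 named genes, alternatives with all libraries or read-share sets gave 1842 values with direction and side of the threshold kept, 182 of the same direction that lost the call, 20 that gained it and 1 reversed. Without 1 library these were 571, 169 and 4. For the lists they were 601, 55, 18 and 21, and without 1 library 203, 9, 8 and 2. Of 120 called named genes, 73 kept the call without each library and 47 lost it without at least 1.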

Other observations

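Removal of the length trend, the scan for genes of 1 library, the test of symbol families and the margin at the threshold for oxidative phosphorylation genes were tests chosen only after the results were seen.

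Other genes of large change were named by the same rule. The matrix protein gene Sparcl1 had 1 read over the Hlf-negative and 2841 over the Hlf-positive libraries, a ratio of 2765 (95% counting interval 495.9 to 109300), or 1069 (191.2 to 42260) without Hlf-positive replicate 1, with 103 CPM in Hlf-positive replicate 1 against 21.5 and 15.1 in the other Hlf-positive libraries. The hydroxysteroid dehydrogenase gene Akr1c14 had 1 and 2197, a ratio of 2138 (383.4 to 84500). The netrin receptor Unc5b rose by 7.52 ± 0.826 on the log2 scale (SE, adjusted p = 0.00281, 6.46 without Hlf-positive replicate 1). The transcription factor Tfec fell from 32.9 ± 5.72 to 3.36 ± 0.910 CPM (−3.29 ± 0.292, adjusted p = 0.00162). The metallothionein Mt1 changed by −3.66 (adjusted p = 0.0111), and by −2.73 without Hlf-negative replicate 3, and its call was lost without Hlf-positive replicate 1 (adjusted p = 0.0563) or 2 (0.055). Each of these genes was separated between the 3 Hlf-positive and the 3 Hlf-negative libraries, as the rule that named them required.

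Genes with an RPKM of at least 10 in 1 library and at least 10 times that of every other library numbered 7 in Hlf-negative replicate 3, 4 in Hlf-positive replicate 1, 2 in Hlf-positive replicate 3 and 0 in each of the other 3. In Hlf-negative replicate 3 they were Spink3 (52.6), S100g (43.8), Ttr (34.3), Rbp4 (21.8), Apoa2 (21.8), Afp (20.5) and Apoa1 (11.9). In Hlf-positive replicate 1 they were Gja5 (97.0), Ctsh (38.2), Tmem100 (24.2) and Mcam (22.5), and in Hlf-positive replicate 3 Lum (53.8) and Dcn (18.4). Among families of at least 8 tested symbols, the Dock guanine exchange factors had 6 of 9 genes higher in Hlf-positive cells, against 1.05 from the share of all genes (hypergeometric adjusted p = 0.0411 over 268 tests). With the share taken from each member's class of transcript length, 1.72 were expected and the adjusted p was 0.332. Of the 9 members, 8 had transcripts over 4000 bases. They were Dock1, Dock2, Dock6, Dock9, Dock10 and Dock11, and their log2 fold changes were 1.05, 1.31, 2.10, 1.97, 2.08 and 1.04. Dock5 was called lower (−0.78, adjusted p = 0.022). Of genes with transcripts over 4000 bases 20.2% were higher, against 2.07% of those under 1000, with median log2 fold changes of 0.20 and −0.82.

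The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1132 genes higher, 439 lower and 23 lists called, and 1 of the 10 splits gave as many for each of the 3 results. The highest of the other splits gave 0 genes higher and 0 lower by edgeR, and 15 lists. Those splits held libraries of both groups on each side, unevenly. Part of the group difference thus stayed between the sides and part added to the spread within them, so they do not measure chance. The split by the share of reads on transcripts gave 0, 0 and 5, with 553 genes at an unadjusted p below 0.05, the most of the other splits, and other tools were not run on the splits.

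The mesenchymal list was higher in Hlf-positive cells, with 1 of its 26 genes also in another list, 2 at an RPKM of 1 in every Hlf-negative library and 11 in every Hlf-positive library. A candidate source is mesenchymal cells among the sorted cells, which would bring their abundant transcripts, although the c-Kit gate would remove cells without c-Kit. The median over Col1a1, Col1a2, Col3a1, Pdgfra, Prrx1 and Twist1 was an RPKM of 6.277 in Hlf-positive libraries and 3.025 without Hlf-positive replicate 3 (called list members 11.66 and 6.601), with Col3a1 at 15.0, 13.8 and 53.4 per library, although Prrx1 was at 0.884 and Twist1 at 3.50 against 2.55 in Hlf-negative libraries. Since 4 of these 6 genes are themselves called members of the list, that level cannot be told apart from expression by the Hlf-positive cells themselves. Without 1 Hlf-positive library the largest adjusted p by camera was 3.03e-07 (1.8e-15 to 0.169 over all alternatives). That test could not decide on a source in 1 library alone, since its 11 tested members reached an RPKM of 1 in every Hlf-positive library. Over all 26 genes, 13, 13 and 18 reached that level in the Hlf-positive and 2, 3 and 2 in the Hlf-negative libraries, which argues against such a source. Tissue and stage stayed open and were not tested.

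The lower lists of housekeeping and stress genes were tested against a length trend and against Hlf-negative replicate 3. With the length trend removed, heat shock genes kept their call (adjusted p = 0.00074, median −0.62 with SD 0.421 before and −0.60 with SD 0.445 after). Without Hlf-negative replicate 3, heat shock (0.000189) and oxidative phosphorylation genes (0.00251) kept theirs. These calls are by camera with the preset correlation. The summed RPKM of heat shock genes was 5593, 5711 and 5419 in Hlf-negative and 3844, 3590 and 3554 in Hlf-positive libraries. For that list the values argue against length or Hlf-negative replicate 3 as the whole cause. For oxidative phosphorylation genes the kept call cannot decide, since fry did not call the list (adjusted p = 0.225). The summed RPKM of oxidative phosphorylation genes was 3101, 3252 and 6182 in Hlf-negative replicates 1, 2 and 3. It was 2311, 2333 and 2692 in Hlf-positive libraries, so the difference was smaller without Hlf-negative replicate 3. For ribosomal protein genes the length correction ended the call (0.154) because the median moved from −1.07 (SD 0.437) to −0.12 (SD 0.396), and without Hlf-negative replicate 3 the call was also lost (0.402), so that library is a candidate explanation. Oxidative phosphorylation genes stayed at 0.0494 after the correction, too near the threshold to decide, with medians of −0.83 (SD 0.460) and −0.16 (SD 0.333), and over all alternatives the lists ranged from 2.95e-26 to 0.691 (ribosomal), 1.61e-11 to 0.435 (oxidative phosphorylation) and 2.65e-05 to 0.211 (heat shock). A length trend cannot be told apart from a change of short transcripts as a class in the ribosomal and oxidative phosphorylation lists, whose median lengths were 703 and 763 bases, and tissue, stage and Hlf status were not tested.

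Hlf-positive libraries held more detected genes. Thinned to 18166318 reads each, they had 13094, 13256 and 13300 symbols with at least 10 reads, against 12360, 12398 and 12594 in Hlf-negative libraries. The gap of 500 between the nearest libraries argues against read depth as the cause, and a gap of 389 without the 100 most abundant genes of each library argues against those genes. Without molecular identifiers, thinning reads does not equalize the number of molecules sampled, so differences in that number stayed open. Tissue, stage, Hlf status and other cell types among the sorted cells stayed open and were not tested.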
